A study of Mus musculus with 28 samples.

How the data were processed

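Regulatory T cells (Tregs) were sorted from mice whose Foxp3 locus drives green fluorescent protein (GFP) and that carried B16 melanoma in the skin. Per the labels, GFP-positive cells with high or low surface OX40 were sorted from tumors and spleens, and RNA was sequenced from 28 libraries. OX40, encoded by Tnfrsf4, is a costimulatory receptor of the TNF receptor family. The groups are called tumor OX40plus, tumor OX40minus, spleen OX40plus and spleen OX40minus after the labels.

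The deposited table is named for counts, but its values are log2 CPM, counts scaled to a common library total. The deposited log2 values have the form of limma's voom transformation, in which 0.5 is added to a count before division by the effective library size. This was read from the values: between 451 and 1325 genes in each library share the library's lowest value, as log2 of 0.5 over the library size gives. Per the submitters' processing notes, bcl2fastq 2.19, kallisto and limma were used with the mouse genome build mm10. How transcripts were summarised to genes, which scaling factor was used, which genes were left out and whether the counting used strand are not given in the sources used here. The lowest value of each library gave its effective size, and inverting the formula gave estimated counts. Between 46.6% and 51.2% of the inverted values per library were whole numbers within 0.01, against 0.885% to 1.29% when the effective size was raised by 10%. kallisto assigns reads that fit several transcripts in fractions, so not every estimated count is whole, and genes with near-identical copies are uncertain.

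The libraries come in pairs with the same mouse and gate in their titles. The 2 libraries of a pair differed by about as much as sampling noise: the median chi-square per gene with at least 20 counts was 0.496 to 0.572 over the 14 pairs, where sampling alone gives 0.455. Libraries of different mice in the same group gave 1.4 to 12.7. Each pair was therefore averaged and counted as 1 sample, which leaves 4 mice per gate for tumors and 3 per gate for spleens, 14 samples in all. Estimated counts per sample ranged from 22.4 M to 29.7 M.

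The plan made before the data were examined assumed counts and a count model. Because the values are log2 CPM, the test used was limma's linear model on the mean log2 CPM of each mouse and gate, with empirical Bayes moderation and a mean-variance trend (limma 3.58.1, R 4.3.3). All 14 samples entered a single fit with 1 term per group and no block. Of 13103 genes in the table, 12548 were tested, those with at least 0.382 CPM in at least 3 samples and at least 15 estimated counts in total. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and every adjusted p for a gene is from this limma fit. The contrasts were OX40plus against OX40minus in tumors and in spleens, tumor against spleen within each gate, and the difference between the OX40 contrasts of the tissues (the interaction). Log2 fold changes are on the log2 CPM scale with 0.5 added to each count and understate changes of genes near 0. They are given with their standard error (SE). CPM values are means with the SD between mice, computed from the estimated counts.

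Of the gene lists, 21 lists of pathways and T cell states and 11 lists of markers of other cell types were fixed before the data were examined, 467 genes in all, of which 394 were tested. The sets were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of each contrast, and again with an estimated correlation. The 3 lists chosen after the results were seen were adjusted together with them, over 34 lists, which does not correct for that choice. Counts of called members are over all genes tested, and the count adjusted over the list alone is given beside them where it differs. Among lists that were not called, the median, mean and test differed in sign for Treg core, cytotoxic effector and melanoma genes in the tumor OX40 contrast, and for dissociation stress, melanoma, B cell and fibroblast genes in the spleen OX40 contrast. They also did for TNF receptors, inhibitory receptors, cytokines and 4 further lists between tissues in OX40plus Tregs (T cell receptor signal, dendritic cell, fibroblast, endothelial). The same held for T cell receptor signal and endothelial genes between tissues in OX40minus Tregs, and for cytotoxic effector and endothelial genes in the interaction. The keratinocyte list had 1 tested gene and was not tested as a list. Genes to be named were also fixed by a rule: the 8 highest and 8 lowest log2 fold changes of each comparison among called genes without overlap between the groups and with at least 10 CPM in the higher group (5 and 5 for the interaction), up to 4 members of each list with the smallest adjusted p, and 14 genes of the Treg literature. Tnfrsf4, predicted gene models, mitochondrial genes and antigen receptor segments stayed out of the ranking. The rule gave 283 genes, and those printed were picked from them after their values were seen. Clock genes, Kdm5d and other genes outside the rule that the closing part names were also chosen after their values were seen. Gene positions are from GENCODE vM21 on mm10, in which all 283 were found by Ensembl identifier. Results for some genes are not reported here.

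For a gene at 0 counts in a whole group, the ratio was computed against a floor of 3 counts over the group. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The steps were tested on simulated counts in which genes were changed by known amounts. A log2 change of 1 was recovered for 65.7% of changed genes in the tumor OX40 contrast over 12458 genes, 52.2% in the spleen OX40 contrast over 12527 genes, 47.8% and 61.2% in the tissue contrasts of OX40plus and OX40minus over 12503 and 12491 genes, and 38.8% in the interaction over 12533 genes. Between 1.01% and 6.49% of the calls in these simulations were on unchanged genes. Each simulation changed 66 or 67 genes by each amount, far fewer genes than were called in the data. Genes were drawn independently, with a spread set by a trend over expression, so these shares need not hold for the real contrasts.

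The titles number the mice, so samples of a tissue with the same number were taken as the same animal. Over 8994 genes with a mean of at least 5 CPM, the deviations of same-numbered OX40plus and OX40minus samples from their group means had correlations of -0.348 to 0.351 within a tissue. The highest correlation within a tissue, 0.508, was between spleen samples with different numbers. Whether a spleen and a tumor with the same number came from 1 animal is not given in the sources used here. The alternatives tried were other scalings (relative log expression factors, library size alone), limma-voom, other filters on low values, only the groups compared, the mouse as a block, only the first or only the second library of each pair, each sample left out in turn, a fold threshold, and, chosen after seeing the data, a pseudocount of 2. No column of the table was left unused. The labels name no sequencing or library batch. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.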

Results

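The study asked how Tregs with high surface OX40 differ from Tregs with low surface OX40 in mouse B16 melanomas, a transplanted skin tumor, and in the spleens of the tumor-bearing mice. RNA-seq gave 4 samples per gate from tumors and 3 per gate from spleens, each the mean of 2 libraries that differed by about as much as sampling noise and were counted as 1 sample. Estimated counts per sample lay between 22.4 M and 29.7 M, so that 3 counts corresponded to 0.104 to 0.13 CPM.

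Tnfrsf4 (chromosome 4, 156013843 to 156016612), which encodes the protein used for sorting, followed the gates. Its level was 253 ± 40.9 CPM in spleen OX40minus Tregs (SD, n = 3), 704 ± 111 in spleen OX40plus (n = 3), 1950 ± 152 in tumor OX40minus (n = 4) and 3357 ± 203 in tumor OX40plus (n = 4). Its mean was thus higher in low-OX40 Tregs of the tumor than in high-OX40 Tregs of the spleen, a difference that was not tested. Foxp3 (chromosome X, 7573644 to 7595245), the transcription factor that defines Tregs, was at 32.5 ± 8.85, 64.5 ± 56.5, 41.9 ± 6.61 and 58.5 ± 4.01 CPM in the same order. Its OX40 difference was called neither in tumors (log2 fold change 0.51 ± 0.33 SE, adjusted p = 0.249) nor in spleens (0.68 ± 0.38 SE, adjusted p = 0.431). The spleen mean rested on mouse 3, whose OX40plus sample had 129.7 CPM against 32.1 and 31.8 in the other mice, and without it the log2 fold change was 0.01. With the tumor groups fitted alone, the tumor difference was called (0.51, adjusted p = 0.0109). The joint fit takes 1 spread per gene from all groups, so the spleen OX40plus sample of mouse 3 also entered the tumor SE.

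**Figure D1:**
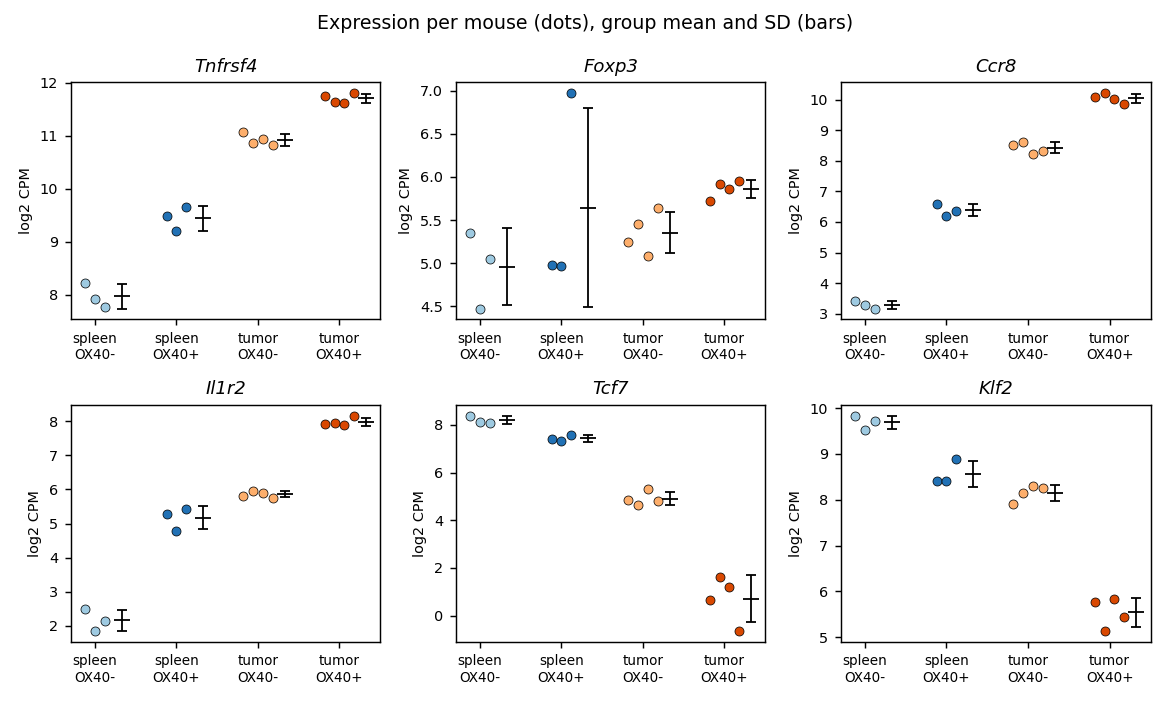
Log2 CPM of 6 genes in every mouse (dots) with the group mean and SD (bars) for the 4 groups on the horizontal axis. Tnfrsf4, Ccr8 and Il1r2 were higher in OX40plus than in OX40minus Tregs of both tissues, Klf2 was lower in both, and Tcf7 was lowest in tumor OX40plus Tregs (1.88 CPM).

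In tumors, OX40plus Tregs carried more Ccr8, Il1r2 and Penk transcripts and more transcripts of cell cycle genes than OX40minus Tregs. They carried fewer transcripts of resting T cell and chemokine receptor genes and of interferon-induced genes. The calls of the cell cycle and interferon lists, unlike those of the resting T cell and chemokine receptor lists, were lost with an estimated correlation between genes (adjusted p = 0.101 to 0.257). Ccr8, a chemokine receptor of tumor Tregs (chromosome 9, 120092114 to 120094906), was at 1067 ± 109 CPM against 347 ± 44.9 (log2 fold change 1.62 ± 0.11 SE, adjusted p = 4.68e-08). Il1r2, the decoy receptor for interleukin-1 (chromosome 1, 40074079 to 40125231), was at 255 ± 23.1 against 58.1 ± 3.57 CPM (2.13 ± 0.15, adjusted p = 5.71e-08). Penk, which encodes the opioid precursor proenkephalin (chromosome 4, 4133531 to 4138819), was at 228 ± 28.3 against 40.5 ± 15.5 CPM (2.55 ± 0.20, adjusted p = 1.55e-07). Tcf7, which encodes the transcription factor TCF1 (chromosome 11, 52252371 to 52283014), fell from 30.5 ± 6.42 to 1.88 ± 1.04 CPM (-4.19 ± 0.33, adjusted p = 2.27e-07).

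Of 17 tested resting T cell genes, 12 were lower and 1 was higher in tumor OX40plus Tregs (median log2 fold change -1.26, camera adjusted p = 9.46e-07, and adjusted p = 0.00687 with an estimated correlation). Besides Tcf7, they included Klf2, which keeps T cells recirculating (chromosome 8, 72319033 to 72321656, -2.61), and its target S1pr1, the receptor for lymphoid exit (-1.64). Ccr7, a lymph node homing gene, was not called (-0.21). Of 16 chemokine receptors, 12 were lower and 1, Ccr8, was higher (median -1.16, adjusted p = 3.52e-06, and adjusted p = 0.0119 with an estimated correlation), among them Ccr4 (-1.97) and Ccr3 (-2.08). The list shares Ccr7 and S1pr1 with the resting T cell list.

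The 24 tested mitosis genes were all higher in tumor OX40plus Tregs (median 1.33, adjusted p = 5.06e-18, but adjusted p = 0.149 with an estimated correlation). The cyclin gene Ccnb1 rose by 1.55 and the proliferation marker Mki67 by 1.05. Of 22 DNA replication genes, 21 were higher, including the helicase genes Mcm5 (1.22) and Mcm6 (0.97), with a median of 1.1 (adjusted p = 1.87e-16, but adjusted p = 0.101 with an estimated correlation). Oxidative phosphorylation genes were higher in 17 of 21 cases (19 adjusted over the list alone), with a median of 0.46, and glycolysis genes in 10 of 15, with 1 lower and a median of 0.42. Atp5g1 rose by 1.01 and Ldha, the lactate dehydrogenase gene, by 0.89, whereas the glucose transporter gene Slc2a3 fell by 0.81. Both metabolic lists passed at the preset correlation (adjusted p = 1.41e-07 and 0.00112) but each had an adjusted p = 0.393 with an estimated correlation.

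Of 23 type I interferon genes, 21 fell (median -1.14, adjusted p = 1.07e-12, but adjusted p = 0.149 with an estimated correlation), such as Ifit3 (-2.37), Rsad2 (-1.80) and Irf7 (-1.29). Of 17 interferon gamma genes, 11 fell and 1 rose (12 fell adjusted over the list alone), with a median of -0.64 (adjusted p = 8.3e-05, but adjusted p = 0.257 with an estimated correlation), including Cd274, the gene of the checkpoint ligand PD-L1 (-1.32), and Cxcl10 (-1.97). Macrophage or monocyte genes moved with these lists. All 11 tested were lower in tumor OX40plus samples (median -1.99, adjusted p = 1.41e-07, but adjusted p = 0.0551 with an estimated correlation), with Apoe at 12.5 ± 4.95 against 98.9 ± 31.3 CPM. Dendritic cell genes were lower in 6 of 9 cases (8 adjusted over the list alone; median -1.13, adjusted p = 0.00406) and NK cell genes in 6 of 8 (median -1.96, adjusted p = 0.00803). With an estimated correlation these 2 lists had an adjusted p = 0.23 and 0.173.

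The Treg lists themselves were mixed in tumors. Among Treg core genes 2 were higher, such as Il2ra, the interleukin-2 receptor alpha chain gene (0.62), and 2 lower, such as Nrp1 (chromosome 8, 128358604 to 128503363, -2.07 ± 0.12), out of 14 (median 0.04, adjusted p = 0.872). Of 17 effector Treg genes 5 were higher and 4 lower (0.15, adjusted p = 0.381), of 12 tumor Treg markers 6 and 3 (0.23, adjusted p = 0.21), and of 11 inhibitory receptors 4 and 4 (0.16, adjusted p = 0.381). Within them, Lag3 (1.71), Havcr2 (1.03), Tnfrsf8 (1.32), Tnfrsf9 (0.33) and Il10 (0.73) were higher and Il1rl1, the interleukin-33 receptor gene (-1.32), and Cd96 (-1.66) were lower. Ctla4 (0.16), Icos (0.19), Tnfrsf18 (0.20) and Klrg1 (0.16) were not called. The lists of TNF receptors (median -0.44), cytokines (-0.63), NF-kB targets (-0.29), T cell receptor signal genes (-0.18), dissociation stress genes (-0.73), hypoxia (-0.12), cholesterol synthesis (0.19), cytotoxic effector genes (-0.13) and tissue repair Treg genes (0.21) were not called. Single members passed, such as Tnfrsf25 (-2.18), Tnfrsf26 (-2.77), Fos (-1.54), Junb (-1.05), the granule genes Nkg7 (1.36) and Prf1 (1.25), and Pparg (1.69). The cholesterol synthesis list was called with the mouse as a block (adjusted p = 0.0493) and with relative log expression factors (adjusted p = 0.0436), but had an adjusted p = 0.474 in the joint fit with an estimated correlation.

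Among the most changed genes of tumor OX40plus Tregs were also Acaa1b (3.29), Flvcr2 (3.16), the histone gene H2bc11 (2.27), Ccdc14 (2.18), the replication origin gene Orc1 (2.14) and Spp1, which encodes osteopontin (2.11). At the other end stood St8sia6 (-5.11), Igfbp3 (-5.11), Slc28a2b (-4.68), the chemokine gene Ccl8 (-4.53), the clock gene Nr1d1 (-4.21), Gbp2b (-4.20) and Prg4 (-3.98). In all, limma called 4823 of 12548 genes between the gates in tumors, 2322 higher and 2501 lower in OX40plus, of which 536 and 987 changed at least as much as a log2 fold change of 1. With relative log expression factors 2489 were higher and 2332 lower, and with the tumor groups fitted alone 2090 and 2037, so which direction had more calls depends on the setting. Tumor OX40plus mouse 4 stood apart from the other mice of its group (median chi-square per gene 6.88 to 12.7, against 4.73 to 6.58 among the others). Its mitochondrial share was 0.906% and its ribosomal protein share 3.16%, against 0.575% to 0.64% and 2.16% to 2.61%, and without it 4571 genes were called. Ccdc14 lost its call without tumor OX40plus mouse 2 (1.97).

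**Figure D2:**
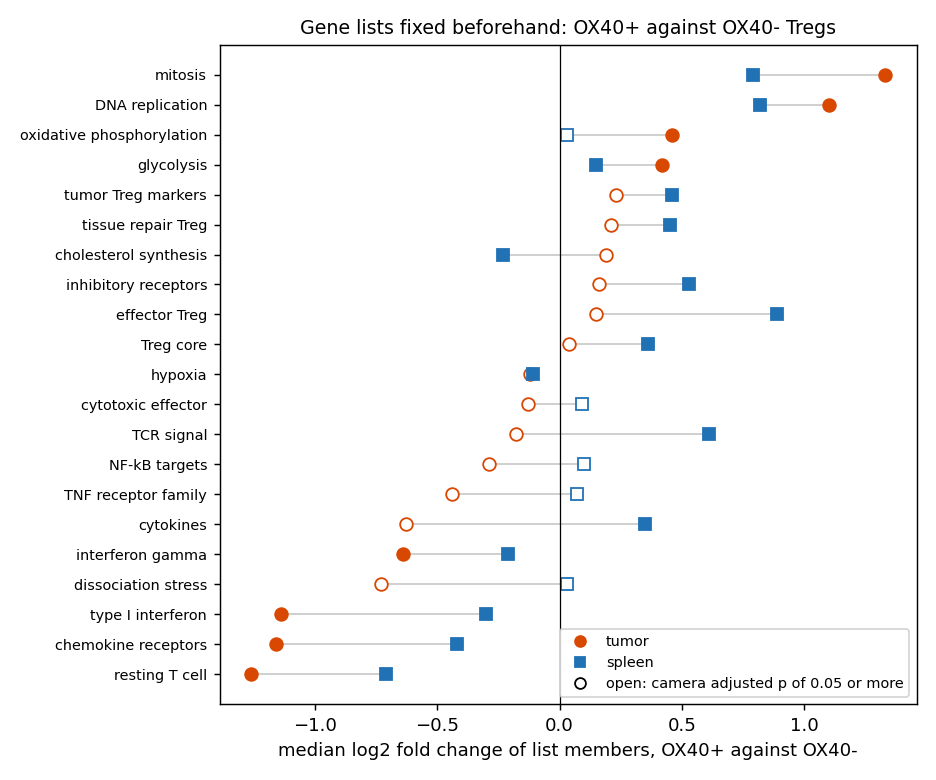
Median log2 fold change of the members of each of 21 gene lists, OX40plus against OX40minus, in tumors (circles) and spleens (squares); filled symbols have a camera adjusted p under 0.05 at the preset correlation. Mitosis and DNA replication genes were higher and resting T cell and chemokine receptor genes lower in both tissues, while the effector Treg list had a median of 0.89 in spleens and 0.15 in tumors. With an estimated correlation, mitosis was called in neither tissue (camera adjusted p = 0.149 in tumors and 0.06 in spleens). DNA replication was then not called in tumors (0.101).

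In spleens, OX40plus Tregs had more transcripts of effector Treg, inhibitory receptor and T cell receptor signal genes than OX40minus Tregs. Ccr8 rose from 9.72 ± 0.805 to 84.3 ± 11.2 CPM (SD, n = 3 each; log2 fold change 3.11 ± 0.13 SE, adjusted p = 8.51e-10). Il1r2 rose from 4.5 ± 0.99 to 36.5 ± 7.98 CPM (3.01 ± 0.17, adjusted p = 2.71e-08) and Penk from 11.8 ± 1.66 to 107 ± 19.8 CPM (3.17 ± 0.23, adjusted p = 4.9e-07). Il10, the gene of the suppressive cytokine interleukin-10 (chromosome 1, 131019845 to 131024974), rose by 2.41, Tnfrsf8 by 2.56 and Tnfrsf9, which encodes the costimulatory receptor 4-1BB, by 2.0. Other genes with high fold changes were F13a1 (2.44), Slc7a10 (3.01) and Gjb2 (2.48).

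Of 17 effector Treg genes, 13 were higher in spleen OX40plus Tregs and none was lower (14 adjusted over the list alone, median 0.89, adjusted p = 1.35e-17, and adjusted p = 0.000326 with an estimated correlation). The members included Klrg1 (1.52) and Icos (0.90). Tumor Treg markers were higher in 6 of 12 cases and lower in 1 (7 and 1 adjusted over the list alone; median 0.46). Inhibitory receptors were higher in 6 of 11 (7 adjusted over the list alone; 0.53), such as Pdcd1, which encodes PD-1 (1.87), Cd200r1 (1.46) and Ctla4 (0.83). T cell receptor signal genes were higher in 8 of 15 (8 higher and 1 lower adjusted over the list alone; 0.61), such as Nr4a2 (1.41), Nr4a3 (0.95) and Tox (0.72). Tissue repair Treg genes were higher in 8 of 16 cases and lower in 1 (9 and 2 adjusted over the list alone; 0.45). With an estimated correlation these lists had an adjusted p = 0.000385, 0.000951, 0.0157 and 0.0178. Treg core genes were higher in 5 of 14 cases (6 adjusted over the list alone; 0.36, adjusted p = 0.000801, but adjusted p = 0.0535 with an estimated correlation), including Tnfrsf18, which encodes GITR (0.93), while Il2ra was not called (-0.17). Cytokine genes were higher in 3 of 14 cases (4 adjusted over the list alone; 0.35, adjusted p = 0.00632, but adjusted p = 0.0766 with an estimated correlation). Areg was at 2.42 against 0.908 CPM and Ifng at 5.87 against 2.77 CPM.

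DNA replication genes were higher in 19 of 22 cases in spleen OX40plus Tregs (21 adjusted over the list alone; median 0.82, and adjusted p = 0.0157 with an estimated correlation), with Cdc6 at 1.24, Mcm5 at 0.99 and Mcm6 at 0.79. Mitosis genes were higher in 20 of 24 (24 adjusted over the list alone; median 0.79, adjusted p = 7.05e-21, but adjusted p = 0.06 with an estimated correlation), with Cdk1 at 1.03 and Tpx2 at 0.78. Mki67 was not called (0.78, adjusted p = 0.0528), but was with the mouse as a block (adjusted p = 0.032) and under several other alternatives. Resting T cell genes were lower in 10 of 17 cases (median -0.71, adjusted p = 4.18e-14, and adjusted p = 0.000238 with an estimated correlation). Examples were Ly6c1 at -1.85, S1pr1 at -0.95, Il6ra at -0.93 and Ccr7 at -0.61. Tcf7 was at 173 ± 15.7 against 298 ± 33.7 CPM and was not called in the joint fit (-0.78, adjusted p = 0.322). It was called with limma-voom and with the spleen groups fitted alone. Chemokine receptors were lower in 8 of 16 cases and higher in 2 (-0.42, and adjusted p = 0.0293 with an estimated correlation).

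Other lists in spleen OX40plus Tregs passed at the preset correlation and not with an estimated one. They were glycolysis (4 of 15 higher, median 0.15, adjusted p = 0.313 with an estimated correlation; Slc16a3 1.09) and cholesterol synthesis (3 of 20 lower, -0.23, adjusted p = 0.129; Sqle -0.71). Interferon lists followed, with type I interferon (1 of 23 lower, -0.30, adjusted p = 0.269) and interferon gamma (4 of 17 lower, 5 lower and 1 higher adjusted over the list alone, -0.21, adjusted p = 0.214). The others were neutrophil genes (1 of 9 lower, -1.03, adjusted p = 0.114) and hypoxia genes (3 of 16 lower, -0.11, adjusted p = 0.217). Irf7, the type I interferon gene called (-0.45, adjusted p = 0.0243), was not called with the mouse as a block (adjusted p = 0.0716), nor was the hypoxia list (adjusted p = 0.0527). With the spleen groups fitted alone neither was called (adjusted p = 0.0611 and 0.0547). The macrophage or monocyte genes were lower in 11 of 11 cases (median -2.75, adjusted p = 1.25e-20, and adjusted p = 0.000951 with an estimated correlation), with Csf1r at 22.2 ± 11.6 against 185 ± 15.2 CPM and Cd68 at -2.75. C1qa and C1qb of this list (-3.67 each) were among the lowest of all genes, beside Gdf15 (-5.32), Slc40a1 (-4.43), Mertk (-4.04), Msr1 (-3.89) and Vcam1 (-3.67), which no list held. B cell genes did not differ between the spleen gates (0 of 8 called, median 0.00).

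In spleens limma called 990 of 12548 genes, 544 higher and 446 lower in OX40plus. The split was 675 and 399 with library size alone, and 495 and 510 with limma-voom. The count was 641 without spleen OX40plus mouse 1, 645 without spleen OX40minus mouse 2, and 1882 with the spleen groups fitted alone. Slc7a10, Slc40a1 and Msr1 lost their calls when any single spleen sample was left out, and Slc40a1 (adjusted p = 0.0737 and 0.0808) and Msr1 (adjusted p = 0.0946 and 0.106) also under both other scalings. Gjb2, Ccr7, Ifng and Irf7 lost theirs without some of the single samples, and Areg, Ifng and Nr4a2 with limma-voom (adjusted p = 0.187, 0.209 and 0.0623).

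Between tissues, the OX40 differences were partly shared. Of the genes called in each tissue, 350 were higher in both, where 101 would be expected for independent lists. Another 317 were lower in both, where 88.9 would be expected (one-sided Fisher's exact test, p = 1.46e-129 and p = 4.9e-126; genes are not independent replicates). A further 49 were called in opposite directions. Across genes, Pearson's r of the log2 fold changes was 0.388 and Spearman's rho 0.381. No library is shared by the contrasts.

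**Figure D3:**
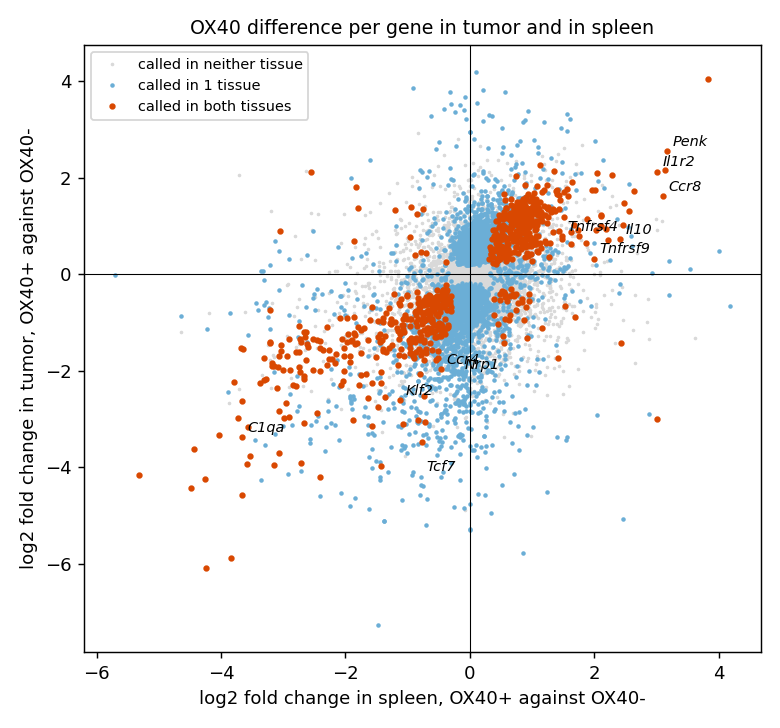
Log2 fold change between OX40plus and OX40minus Tregs for every tested gene in spleens (horizontal axis) and tumors (vertical axis), colored by the tissues in which it was called. Penk, Il1r2 and Ccr8 lie high on both axes, and Tcf7 (-0.78 and -4.19) and Nrp1 lie low on the tumor axis.

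The interaction asked which OX40 differences were themselves different in tumor and spleen, with positive values where the difference was more positive in tumors. Tnfrsf4, whose protein was used for sorting, itself had a smaller OX40 difference in tumors (-0.69, adjusted p = 0.0168). Whether this accounts for the differences of other genes was not tested. Lists of Treg activation had smaller or more negative OX40 differences in tumors. With an estimated correlation the differences were called for effector Treg genes (9 of 17 lower, 14 adjusted over the list alone, median -0.77, adjusted p = 0.00379) and tumor Treg markers (8 of 12 lower, -1.08, adjusted p = 0.00379). They were also called for TNF receptors (6 of 11, -0.74, adjusted p = 0.0214), inhibitory receptors (5 of 11, -0.67, adjusted p = 0.0214) and chemokine receptors (9 of 16, 1 higher, -0.83, adjusted p = 0.0214). Such a call was also made for T cell receptor signal genes (9 of 15, 10 adjusted over the list alone, 2 higher; -0.90, adjusted p = 0.0387). Examples were Tnfrsf9 (-1.67 ± 0.14 SE, adjusted p = 6.97e-06), Il10 (-1.68), Ccr8 (-1.48), Klrg1 (-1.36) and Pdcd1 (-1.21). Their mean levels in tumor OX40minus Tregs were above those in spleen OX40plus Tregs, as for Tnfrsf9 (2573 ± 195 against 471 ± 62.7 CPM). Nrp1 was lower in OX40plus in tumors and not called in spleens (-0.18; interaction -1.89, adjusted p = 1.89e-05). Ccr4 was lower in OX40plus by a larger amount in tumors (-1.51), while Cxcr3 (-1.24) was lower in OX40plus in tumors and higher in spleens.

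Type I interferon genes had a more negative OX40 difference in tumors in 15 of 23 cases (20 adjusted over the list alone; median -0.79, adjusted p = 3.01e-10, but adjusted p = 0.114 with an estimated correlation), such as Ifit3 (-1.80) and Rsad2 (-1.41). Dendritic cell (3 of 9 lower, 5 adjusted over the list alone; -1.29, adjusted p = 0.00886) and NK cell genes (1 of 8 lower, -1.52, adjusted p = 0.0365) moved the same way, but had an adjusted p = 0.199 and 0.2 with an estimated correlation. The NK cell call was also lost without mouse 3 of either spleen gate or tumor OX40plus mouse 1 or 2 (-1.44 to -1.11), and from the first libraries alone (-1.10). In the other direction, Satb1, a chromatin organiser of T cells, was higher in OX40plus in tumors (300 ± 32.1 against 175 ± 13.6 CPM) and lower in spleens (161 ± 27.8 against 310 ± 11 CPM; interaction 1.74 ± 0.16, adjusted p = 1.26e-05). Il2ra (0.80), Sqle (1.14), Prf1 (2.11), Ccl4 (2.09) and Ube2c (0.89) were also positive. The highest differences were those of Spp1 (4.67), Slc11a1 (3.93), Trpm2 (3.82), Galnt3 (3.63) and Ptgs1 (3.56), and the lowest those of Slc7a10 (-6.01), Btk (-4.58), Fam160a1 (-4.24), Gucy1a1 (-4.18) and F13a1 (-3.86). Limma called 1357 genes, 563 higher and 794 lower, and 766 without spleen OX40plus mouse 1 or 829 without spleen OX40minus mouse 2. The balance of directions depended on the scaling, with 702 higher and 705 lower under relative log expression factors and 467 and 998 with library size alone. With the mouse as a block, Fam160a1 (adjusted p = 0.0659) and Gucy1a1 (adjusted p = 0.077) were not called, and both lost their calls without some of the single samples. Fam160a1 was not called under either other scaling (adjusted p = 0.0536 and 0.0517), nor Areg with limma-voom (adjusted p = 0.0616).

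Tumor Tregs of both gates differed from spleen Tregs by higher effector, tumor Treg, glycolysis and hypoxia genes and lower resting T cell genes. The glycolysis and hypoxia lists, unlike the others, lost their calls with an estimated correlation (adjusted p = 0.0735 to 0.192). Transcripts of the 13 mitochondrially encoded protein genes made up 1.13% to 1.53% of the estimated counts in spleen samples and 0.538% to 0.906% in tumor samples. In OX40plus Tregs, Ccr8 was higher in tumors by a log2 fold change of 3.66 ± 0.12 SE (adjusted p = 7.61e-13), Il10 by 3.12, Tnfrsf9 by 2.78 and Ctla4 by 2.31, and in OX40minus Tregs by 5.15, 4.80, 4.45 and 2.99. Bnip3, a hypoxia-induced mitophagy gene (chromosome 7, 138890836 to 138909519), was at 253 ± 23.9 against 5.49 ± 0.523 CPM in OX40plus and 152 ± 10.3 against 5.01 ± 0.735 CPM in OX40minus Tregs. Tcf7 was lower by -6.72 and -3.30 in tumor OX40plus and OX40minus Tregs, and the survival gene Bcl2 by -3.54 and -2.69.

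Effector Treg genes were higher in tumors in 12 of 17 cases and lower in 3 in OX40plus Tregs (median 1.66, adjusted p = 0.0416 with an estimated correlation). In OX40minus Tregs 14 were higher and 3 lower (2.42, adjusted p = 0.00738). Examples were Id2 (3.60 and 4.13) and Gzmb, the granzyme B gene (2.85 and 3.47). Tumor Treg markers were higher in 9 of 12 in each gate, with 2 lower in OX40plus (1.98 and 2.51, adjusted p = 0.031 and 0.00738 with an estimated correlation). Tissue repair Treg genes were higher in 12 and 14 of 16 and lower in 1 and 2 (13 and 14 higher adjusted over the list alone; 1.46 and 1.63, adjusted p = 0.0487 and 0.0198), including Areg, the gene of the growth factor amphiregulin (5.15 and 7.10). Resting T cell genes were lower in 13 and 12 of 17, with 3 higher in OX40plus (-1.28 and -1.36, adjusted p = 0.031 and 0.00791 with an estimated correlation).

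Glycolysis genes were higher in tumors in 14 and 15 of 15 cases in OX40plus and OX40minus Tregs (medians 2.17 and 2.04, adjusted p = 7.3e-09 and 8.64e-10, but adjusted p = 0.123 and 0.0735 with an estimated correlation). Examples were Tpi1 (3.42 in each) and Ldha (3.35 and 2.57). Hypoxia genes were higher in 10 and 11 of 16 and lower in 2 and 3 (1.21 and 1.31), DNA replication genes in 21 and 21 of 22 (1.58 and 1.30). Mitosis genes were higher in 23 and 23 of 24, with 1 lower in OX40minus (1.78 and 1.38) and oxidative phosphorylation genes in 21 and 17 of 21 (21 and 18 adjusted over the list alone; 1.12 and 0.64). Cholesterol synthesis genes were higher in 14 and 11 of 20 and lower in 3 and 3 (14 and 12 higher and 3 and 4 lower adjusted over the list alone; 0.93 and 0.46; Idi1 2.78 in OX40plus). Cytotoxic effector genes were higher in 7 and 8 of 14 and lower in 4 and 1 (4 and 2 lower adjusted over the list alone; 1.80 and 1.91; Nkg7 4.91 and 4.50). Dissociation stress genes were higher in 10 and 10 of 14 and lower in 1 and 2 (0.68 and 1.03). These lists passed at the preset correlation and not with an estimated one, where the adjusted p was 0.181 and 0.192 for hypoxia, 0.181 and 0.166 for DNA replication, 0.231 and 0.265 for mitosis. It was 0.277 and 0.312 for oxidative phosphorylation, 0.229 and 0.312 for cholesterol synthesis, 0.181 and 0.0902 for cytotoxic effector genes and 0.42 and 0.312 for dissociation stress. Mki67 did not follow the mitosis list, with -0.28 (not called) in OX40plus and -0.55 (adjusted p = 0.0398) in OX40minus Tregs. The OX40minus call was lost when any of 5 of the 7 samples was left out. In OX40plus a call was gained without spleen mouse 3 (-0.60, adjusted p = 0.0103). In OX40minus Tregs, chemokine receptors (9 of 16 higher and 3 lower, 1.11), NF-kB targets (12 of 17 higher and 4 lower, 0.84) and interferon gamma genes (11 of 17 higher and 1 lower, 2 lower adjusted over the list alone, 1.04) were also called at the preset correlation, with an adjusted p = 0.0735, 0.216 and 0.265 with an estimated correlation. In both gates Cxcr6 (5.54 and 5.27) and Ccr2 (3.65 and 3.62) were higher in tumors. Type I interferon genes were lower in 18 of 23 cases in OX40plus Tregs (-0.95, adjusted p = 0.000108, but adjusted p = 0.331 with an estimated correlation) and went both ways in OX40minus Tregs, with 10 lower and 5 higher (Irf7 -0.81, Ifit1 1.06).

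Markers of other cells differed between the tissues. B cell genes were lower in tumor samples in 8 of 8 cases in each gate (adjusted p = 0.0274 and 0.00738 with an estimated correlation). Melanoma genes were higher in tumor samples in 8 and 9 of 11 cases, with 1 lower in OX40minus (2.25 and 2.53, adjusted p = 0.00545 and 0.0117, but adjusted p = 0.181 and 0.217 with an estimated correlation). Tyrp1 was at 40.6 ± 5.78 and 40.7 ± 19.1 CPM in tumor OX40minus and OX40plus samples. Of 11 macrophage or monocyte genes, 6 and 7 were lower in tumor OX40plus and OX40minus samples, and 1 was higher in OX40plus. The OX40minus list call (-1.27, adjusted p = 0.046) was lost under either other scaling (-1.11 each) and with an estimated correlation (adjusted p = 0.312). The erythroid (1.72 and 2.64), fibroblast (-0.11 and 2.35), endothelial (0.54 and 0.11), neutrophil (-2.0 and -1.89), NK cell (-3.08 and -1.93), dendritic cell (-0.17 and 0.98) and CD8 T cell lists (-0.62 and 0.33) were not called. The hemoglobin gene Hba-a2 was higher in tumors in each gate (3.76 and 3.84).

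**Figure D4:**
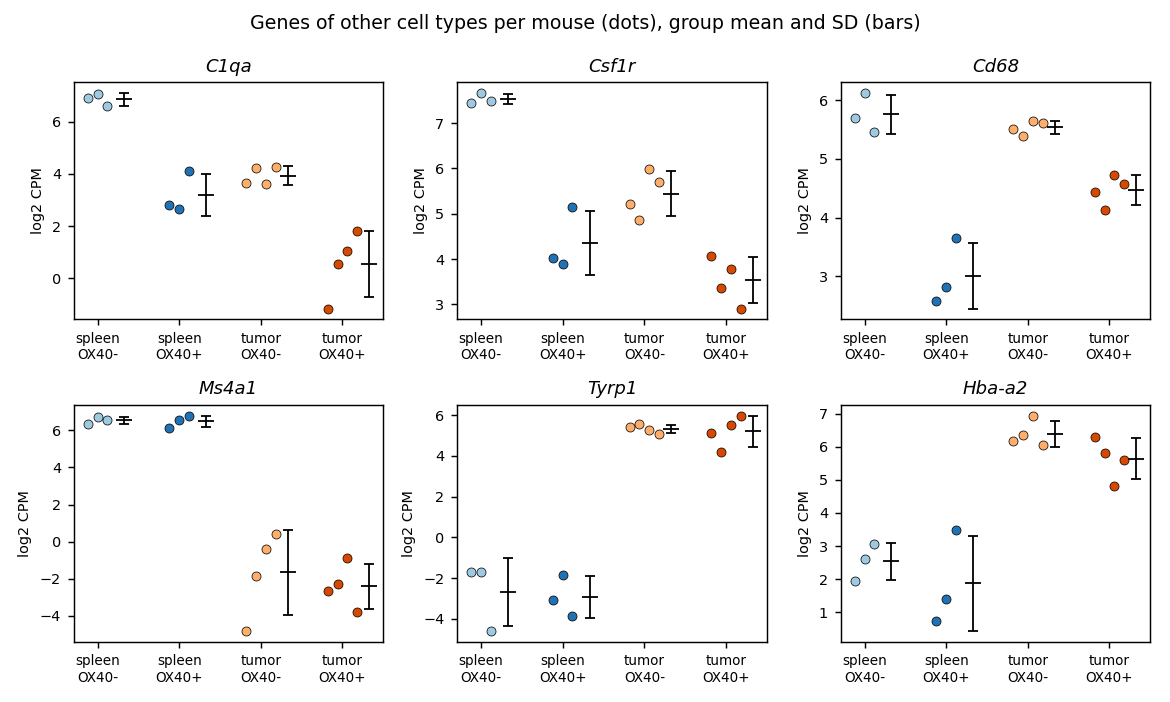
Log2 CPM of genes of macrophages (C1qa, Csf1r, Cd68), B cells (Ms4a1), melanoma (Tyrp1) and red cells (Hba-a2) in every mouse (dots) with the group mean and SD (bars). Ms4a1 is low in tumors, Tyrp1 is low in spleens, and C1qa, Csf1r and Cd68 are lower in OX40plus than in OX40minus samples of each tissue.

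Among the highest fold changes in tumors of both gates were those of Hist1h2ap (8.87 and 8.93), a histone gene with near-identical copies, so that its own level is uncertain. Replication-dependent histone genes, a list chosen after the results were seen, were higher in tumors in 23 and 15 of 29 cases and lower in 1 and 1. Their medians were 2.06 and 1.70 (camera adjusted p = 3.52e-05 and 0.00297, but adjusted p = 0.181 and 0.259 with an estimated correlation). Tsix (8.48 and 8.29) overlaps Xist on the other strand, and whether the counting used strand is not given in the sources used here. Cd209a (8.23 and 9.95) followed, and Snord13 was at least 262-fold higher in tumor than in spleen OX40plus samples. Spp1 (7.11) and Ermn (6.55) in OX40plus and Ccl8 (7.87), Ccl22 (6.57) and Tgfa (6.41) in OX40minus Tregs also ranked high. Limma called 8090 of 12548 genes between tissues in OX40plus Tregs, 3791 higher and 4299 lower in tumors, and 7403 in OX40minus Tregs, 3722 higher and 3681 lower. Any difference in handling or RNA quality between tumor and spleen samples cannot be told apart from tissue here. The OX40minus split was 3567 and 3764 with relative log expression factors, 3587 and 3759 with library size alone, and 3632 and 3878 with limma-voom. The median log2 fold change of all genes in OX40plus Tregs was -0.13, and -0.24 with library size as the only scaling, under which Ccr7 was no longer called (0.29, adjusted p = 0.0613, against 0.39). Ccr7 also lost this call without either of spleen mice 1 and 2 or tumor mice 2 and 3.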

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

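In each tumor group of 4 mice, every printed gene was checked for a mouse far from the other 3 relative to the range of the group. Of 266 such checks 16 found one, close to the share of about 1 in 20 that chance gives. The single cases below may therefore be chance. In tumor OX40minus Tregs, mouse 2 was low for Il2ra (log2 CPM 9.79, against 9.96 to 9.98 in the others) and high for Mcm6 (8.93, against 8.69 to 8.71). Mouse 3 was high for Klrk1 (5.42, against 4.81 to 4.86), and mouse 4 was high for Nr1d1 (4.39, against 3.89 to 3.91). Genes at or near 0 counts in the other mice stood out for Cd5l (-3.65) and Pax5 (-3.22) in mouse 3 and for Exosc6 in mouse 2 (-1.59).

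In tumor OX40plus Tregs, mouse 1 was low for Cd96 (log2 CPM 3.33, against 4.12 to 4.23). Mouse 2 was low for Tnfrsf25 (3.52, against 4.44 to 4.53) and high for Tpx2 (7.73, against 7.54 to 7.57). Mouse 4 was low for Tox (6.76, against 7.06 to 7.09) and Fam160a1 (-3.93, against 0.86 to 1.70), and high for Tnfrsf26 (3.07, against 1.63 to 1.87). Mouse 3 was above the others, which were at or near 0 counts, for Slc7a10 (-0.99), Fcrla (-2.33) and Tlr9 (-3.74).

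The OX40 difference itself differed between tumor and spleen, by limma's interaction term, for 64 of the printed genes. It was more negative in tumors for Tnfrsf4 (-0.69), whose protein was used for sorting. Among other receptors of activated Tregs it was also more negative for Tnfrsf8 (-1.24), Tnfrsf9 (-1.67), Tnfrsf18 (-0.74), Tnfrsf25 (-1.67), Tnfrsf26 (-1.90) and Ctla4 (-0.67). The same held for Icos (-0.71), Pdcd1 (-1.21), Cd96 (-1.38), Cd200r1 (-1.34), Klrg1 (-1.36), Il1r2 (-0.88), Il1rl1 (-1.12) and Nrp1 (-1.89). Chemokine and homing receptors with a more negative value were Ccr3 (-1.28), Ccr4 (-1.51), Ccr8 (-1.48), Cxcr3 (-1.24) and S1pr1 (-0.69). Among secreted factors Il10 (-1.68), Areg (-1.95), Ifng (-1.63), Mmp9 (-2.02) and Prg4 (-2.55) were negative and Ccl4 (2.09) and Spp1 (4.67) positive.

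Transcription factors with a more negative OX40 difference in tumors were Tcf7 (-3.41), Klf2 (-1.49), Gata3 (-0.89), Tox (-0.74), Nr4a2 (-1.37), Nr4a3 (-1.36), Fos (-1.26) and Junb (-0.90), and those with a more positive one were Satb1 (1.74) and Pparg (1.80). Interferon-related genes were negative: Ifit3 (-1.80), Rsad2 (-1.41), Irf7 (-0.84), Cxcl10 (-2.07), Cd274 (-1.11), Cd74 (-1.05) and Gbp2b (-1.80). Metabolic and transport genes went both ways, with Slc2a3 (-0.79), Slc28a2b (-3.58) and Slc7a10 (-6.01) negative and Ldha (0.78), Sqle (1.14), Acaa1b (2.94), Ptgs1 (3.56) and Slc11a1 (3.93) positive. The others were Btk (-4.58), Fam160a1 (-4.24), Gucy1a1 (-4.18), F13a1 (-3.86) and St8sia6 (-3.73) with negative values and Il2ra (0.80), Ube2c (0.89), Cd68 (1.68), Prf1 (2.11), Vcam1 (2.14), Galnt3 (3.63) and Trpm2 (3.82) with positive values.

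The interaction was called for 18 gene lists at the preset correlation. Besides effector Treg genes (median -0.77), tumor Treg markers (-1.08), TNF receptors (-0.74), inhibitory receptors (-0.67), chemokine receptors (-0.83) and T cell receptor signal genes (-0.90), which kept the call with an estimated correlation, these were the following. Treg core (-0.36), cytokine (-1.31), NF-kB target (-0.35), tissue repair Treg (-0.57), type I interferon (-0.79), interferon gamma (-0.19), dendritic cell (-1.29) and NK cell genes (-1.52) had more negative OX40 differences in tumors. Mitosis (0.50), DNA replication (0.25), cholesterol synthesis (0.46) and oxidative phosphorylation genes (0.38) had more positive ones. With an estimated correlation the adjusted p of these 12 lists ranged from 0.0552 to 0.435.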

How the results depend on the processing

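The pseudocount of 2 and the fit of the ribosomal protein, histone and clock lists without tumor OX40plus mouse 4 were chosen after seeing the data, and the other alternatives before. No gene or list result reversed under any alternative that was run. Which direction had more called genes did turn in the tumor OX40 contrast (relative log expression factors, 2489 higher and 2332 lower; tumor groups alone, 2090 and 2037) and the spleen OX40 contrast (limma-voom, 495 and 510). It also turned between tissues in OX40minus, with these factors (3567 and 3764), library size alone (3587 and 3759), limma-voom (3632 and 3878) and without tumor mouse 3 (3526 and 3540). In the interaction it went from 563 higher and 794 lower to 702 and 705 with relative log expression factors and to 467 and 998 with library size alone. A planned DESeq2 test was not run, since the table holds log2 CPM and counts could only be estimated from it. Limma-voom was run on these estimated counts, but no count model was tried on them. Fitting only the groups compared does not apply to the interaction, which needs all of them. At 22.4 M to 29.7 M estimated counts per sample, levels below about 0.104 to 0.13 CPM could not be told from 0.

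Requiring a log2 fold change of at least 1 as well left 1523 genes in the tumor OX40 contrast, 415 in the spleen OX40 contrast, 4874 and 3936 between tissues in OX40plus and OX40minus, and 499 in the interaction, because it is stricter by construction. With only the groups compared in the fit, the spleen OX40 contrast called 1882 genes in place of 990. Foxp3 was then called in tumors with the same log2 fold change of 0.51. The joint fit takes 1 spread per gene from all groups. For Foxp3 the deviating spleen OX40plus mouse 3 thus enters the error of the tumor contrast. How far the spread, the genes tested and the adjustment each account for the counts was not tested. Leaving out 1 sample at a time gave 4264 to 4828 genes in the tumor and 641 to 842 in the spleen OX40 contrast, 7296 to 8063 and 6440 to 7174 in the tissue contrasts, 766 to 1628 in the interaction, and 453 to 769 shared between the OX40 contrasts. The spleen count fell to 641 without spleen OX40plus mouse 1 and to 645 without spleen OX40minus mouse 2, and the interaction to 766 and 829 without the same samples. These fits have fewer samples. Foxp3 in spleens ranged from 0.01 without OX40plus mouse 3 to 1.01, and without that mouse Foxp3 was called between tissues in OX40plus (0.89). With the mouse as a block, the counts were 4484, 857, 7930, 7265, 960 in the interaction and 577 shared.

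Of 236 gene results, leaving out 1 sample ended a call in 57 of 1935 refits and gave one in 4. The genes that lost a call were Ccdc14 in tumors without OX40plus mouse 2 (1.97), and in spleens Slc7a10 (2.87 to 3.20), Slc40a1 (-4.52 to -4.25) and Msr1 (-4.05 to -3.61) without any spleen sample. Gjb2 lost its call without spleen OX40minus mouse 3 (2.35) or OX40plus mouse 1 (2.37). Ccr7 did without OX40minus mouse 1 (-0.53) or OX40plus mouse 1 or 2 (-0.55 and -0.59). Ifng did without OX40minus mouse 2 or 3 (0.84 and 1.20) or OX40plus mouse 1 or 3 (1.04 and 0.92), and Irf7 without OX40minus mouse 1 or 2 (-0.36 and -0.39) or OX40plus mouse 1 or 2 (-0.42 and -0.46). Between tissues, Ccr7 in OX40plus lost its call without spleen mouse 1 or 2 (0.33 and 0.37) or tumor mouse 2 or 3 (0.33 and 0.32). Mki67 in OX40minus did without spleen mouse 2 or 3 (-0.41 and -0.52) or tumor mouse 1, 3 or 4 (-0.56, -0.48 and -0.50). In the interaction, Tnfrsf18 lost its call without spleen OX40minus mouse 2 (-0.69), Fam160a1 without any spleen or tumor OX40minus sample (-4.38 to -4.09), and Gucy1a1 without spleen mouse 1 or 2 of either gate (-4.20 to -4.11) or tumor OX40minus mouse 4 (-3.76). With limma-voom, Areg and Ifng (interaction also for Areg) and Nr4a2 lost their spleen calls, and Tcf7 and Mki67 gained one. Under both other scalings Slc40a1 (-4.43 and -4.38) and Msr1 (-3.90 and -3.85) lost their spleen calls and Fam160a1 its interaction call (-4.25 and -4.37). With library size alone Ccr7 lost its call between tissues in OX40plus (0.29). With only the groups compared, Irf7 lost its spleen call and Tcf7 gained one. From the first libraries alone Msr1 (-3.77) and Ifng (0.97) lost their spleen calls, and from the second alone Slc7a10 did (3.08) and Gucy1a1 lost its interaction call (-4.00). The mouse as a block ended the calls of Irf7 in spleens and of Fam160a1 and Gucy1a1 in the interaction. Mki67 also gained a spleen call with the mouse as a block, with a filter of 1 CPM and from either library alone. Among 155 list results, leaving out 1 sample ended a call in 17 refits of 1302 and gave one in 13. The lists that lost a call were hypoxia and neutrophil genes in spleens, macrophage genes between tissues in OX40minus, and interferon gamma and NK cell genes in the interaction. Under the other settings, hypoxia genes in spleens lost their call with only the groups compared, with the mouse as a block and from the first libraries alone, which also ended those of neutrophil genes in spleens and of NK cell genes in the interaction. Macrophage genes between tissues in OX40minus lost theirs under both other scalings, without a filter, from either library alone and with a pseudocount of 2. Calls were gained by cholesterol synthesis in tumors (relative log expression factors, mouse as a block), endothelial genes in spleens (library size alone, only the groups compared), NF-kB targets between tissues in OX40plus (library size alone, limma-voom) and Treg core genes between tissues in OX40minus (limma-voom, only the groups compared).

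Without tumor OX40plus mouse 4, ribosomal protein genes were higher in 52 of 65 cases in tumor OX40plus Tregs (median 0.53) and histone genes in 18 of 29 (1.53), and clock genes were lower in 7 of 15 (-0.65).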

Other observations

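The lists of clock, histone and ribosomal protein genes, Kdm5d and the tests on ribosomal protein genes, on the scaling of macrophage genes and on the interaction without the shared OX40 difference were chosen after the results were seen. Circadian clock genes were lower in 8 of 15 cases in tumor OX40plus Tregs and higher in none (median log2 fold change -0.59, camera adjusted p = 0.000312, and adjusted p = 0.0223 with an estimated correlation). They included Nr1d1 (-4.21), Dbp (-1.72), Nr1d2 (-1.20), Bhlhe40 (-1.12) and Per1 (-1.04). Nr1d1 was already among the lowest genes of this contrast, and no adjusted p of this list corrects for its choice from the same data. In spleens 2 were higher and 2 lower (-0.06, adjusted p = 0.657), and the interaction was called (-0.45, and adjusted p = 0.0195 with an estimated correlation).

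Replication-dependent histone genes were higher in 21 of 29 cases in tumor OX40plus Tregs (median 1.63, adjusted p = 3.67e-07, but adjusted p = 0.122 with an estimated correlation). Their near-identical copies make the single members uncertain. Ribosomal protein genes were higher in 58 of 65 (median 0.63, adjusted p = 1.52e-15, but adjusted p = 0.419 with an estimated correlation). Their share of the estimated counts was 3.16% in tumor OX40plus mouse 4 and 2.16% to 2.61% in the other mice of the group, and without that mouse 52 of 65 were higher (0.53). Kdm5d, a gene of the Y chromosome, had a log2 CPM of 2.22 to 2.67 in spleen samples and 1.30 to 1.97 in tumor samples.

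Macrophage or monocyte genes were lower in OX40plus samples in 11 of 11 cases in each tissue, with Csf1r at 185 ± 15.2 CPM and C1qa at 117 ± 18.8 CPM in spleen OX40minus samples (SD, n = 3). None of the 11 genes is in another list, and all had at least 1 CPM in every group. The other scalings do not account for the difference, since over both tissues and both of them the median log2 fold change nearest 0 was -2.08. A scaling shifts all genes of a sample alike, and under these the median of all genes stayed between -0.10 and 0.05. They could thus move the list little, whatever its source. The deviations of these genes from their group means went together over the 14 samples, with a median correlation of 0.187, at percentile 98.52 of random lists of like expression, so RNA or cells of macrophages in the OX40minus samples are a candidate source. Expression of these genes by OX40minus Tregs themselves was not tested, and sorting on GFP would remove macrophages unless they carried GFP or stuck to sorted cells.

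B cell genes were found in spleen samples and melanoma genes, such as Tyrp1, in tumor samples. None of the 8 and 11 tested members is in another list, and 1 and 4 of them had at least 1 CPM in every group. The B cell genes went together over the 6 spleen samples (median correlation 0.791, percentile 99.23 of random lists), and 9 melanoma genes did over the 8 tumor samples (0.51, percentile 100). RNA or cells of B cells and of the melanoma may therefore be present in the respective samples, although the gate on GFP would remove both. Differences between tissues in the Tregs themselves stay open, as untested.

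Ribosomal protein genes were lower in tumor samples, in 55 of 65 cases in OX40plus and 61 of 65 in OX40minus, with 2 higher in each (medians -1.33 and -2.08, but adjusted p = 0.435 and 0.259 with an estimated correlation). Transcripts of the 13 mitochondrially encoded protein genes moved the same way, with 0.538% to 0.906% of the estimated counts in tumor and 1.13% to 1.53% in spleen samples. Transcript length alone does not account for it, since 545 other genes of like length had a median of 0.18, which is -8.654% of the ribosomal protein median in the gate where this share was larger. The other scalings do not either, with a median nearest 0 of -1.31. Under them the median of all genes stayed between -0.24 and -0.06, so they could move this list little, whatever its source. Single ribosomal protein genes went far in both directions in OX40plus, such as Rps10 (-4.80) and Rps18 (2.26). How reads were divided among near-identical copies was not tested. A difference in RNA quality and one between tumor and spleen Tregs stay open, as untested.

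Other splits of the samples were counted for each contrast. For the tumor OX40 contrast, 1 of 35 splits of the 8 samples gave as many genes, the real one with 4823, and the highest other gave 19. That share is under 0.05 but is the lowest that 35 splits allow. The other splits also mix the real groups and add their difference to the spread, so chance is not excluded. The 7 others that part as many mouse pairs gave at most 19 and are too few for a share under 0.05. In spleens the 10 splits of the 6 samples are too few for a share under 0.05, with 990 genes for the real split and 0 for the highest other. For the tissue contrasts 1 of 35 splits gave as many in each gate, the real one, with 8090 against at most 5566 in OX40plus and 7403 against at most 4452 in OX40minus. This share is again the lowest possible and the other splits mix the tissues, so chance is not excluded. For the interaction, regrouping the values as they are within tissues decides nothing, since it breaks the OX40 difference shared by the tissues and adds it to the spread. There 2 of 100 drawn regroupings gave as many genes, the real one with 1357 and another with 1853. In that one all 8 tumor samples had their labels exchanged, which leaves the tumors split as they are, and 4 of 6 spleen samples kept theirs. With the shared OX40 difference removed from every gene, 1 of the same 100 splits gave as many, the real one with 1357, and the highest other gave 275. The removed difference was estimated with the real labels, so the real count could not change by it. This count was also chosen after the first was seen, so chance is not excluded.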
